A study of Mus musculus with 17 samples.

How the data were processed

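The deposited table holds log2 expression values of 45141 probe sets in 17 arrays, which per the submitters' processing notes were computed with Partek and RMA. The values ran from 0.492 to 12.9 with a median of 4.71. Per the labels, cells were sorted by flow cytometry to a purity over 99% directly into lysis buffer, and the RNA was amplified and labelled with biotin. The RNA samples had RIN scores over 8 apart from 3 samples with scores of 7.8, 7.7 and 7.2, whose numbers could not be matched to arrays. Groups were taken from the sample titles: B cells and CD4 T cells of the lacrimal gland (4 arrays each), B cells and CD4 T cells of the spleen (3 each) and epithelial cells of the lacrimal gland (3). Arrays were taken as independent, since the labels do not say whether equal replicate numbers pair the samples.

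Probe sets were named from a table of the array platform's annotation, with symbols brought up to date by gene identifier (assembly GRCm38.p6, used for names only). Of the probe sets 104 were controls, 28898 had exactly 1 gene (28689 matched by identifier), 551 had several and 15588 were not listed. For each gene the probe set with the highest mean over all arrays was kept, which gave 17097 genes; dim genes were not filtered out. Genes without a probe set of their own were not analysed here.

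A linear model with a mean for each of the 5 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with 12 residual and 3.17 prior degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes and a fold change of at least 2. In the comparison of epithelium with the mean of gland B and CD4 T cells, a gene called higher also needed a higher mean in epithelium than in each subset. The other comparisons were gland against spleen in B cells and in CD4 T cells, the difference between these changes, and B against CD4 T cells within the gland. Fold changes are differences of group means on the log2 scale, with the standard error from the model. Errors beside group means are standard deviations between arrays. Overlaps were set beside the number expected for independent sets, and correlations were computed across genes.

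Before the data were examined, the groups, comparisons, thresholds, alternatives, the rule for named genes and 47 gene lists were fixed; the lists held 644 genes, of which 544 were measured. The 43 lists with at least 5 measured genes were tested with limma's camera at its preset correlation of 0.01, Benjamini-Hochberg adjusted within a comparison, and again with the correlation estimated for each list and with fry. Members were counted over all genes tested and adjusted over the list alone. The rule for named genes took, among called genes with no overlap between the groups' arrays and with the higher mean above the median of all values, the 10 largest increases and 10 largest decreases for each gland against spleen comparison. It took 5 and 5 for B against CD4 T cells and, without the condition on overlap, for the difference of the changes, and the 20 largest increases for epithelium. Antigen receptor segments and unnamed gene models were left out of these. From every list it took up to 4 called genes with the largest change, and list members needed to describe what did not pass; lineage and sex-linked genes were named as a check of the labels. Foxp3 lay outside the rule.

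The pipeline was tested on simulated data built from the arrays' own spread. For a shift of 2 on the log2 scale it recovered 95.5% to 100% of the shifted genes across the 5 comparisons, with 0 to 2 false calls among 17097 genes. The simulated noise was normal and independent between genes and arrays. False calls from correlated genes or from single arrays that stand apart were therefore not tested. The median standard error of a fold change was 0.121 for gland against spleen in either subset, 0.172 for the difference of the changes, 0.108 for epithelium and 0.112 for B against CD4 T cells; the number of arrays limits this precision. Correlations between arrays of a group ran from 0.977 to 0.996.

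The alternatives tried were no fold change minimum, a filter keeping genes above the median of all values in at least 3 arrays, all probe sets or the mean of a gene's probe sets, centring on array medians, quantile normalization, eBayes with trend and robust settings, array weights, replicate numbers as a block, only the arrays of the groups compared, leaving out each array in turn, and gland against spleen without genes at least 4-fold higher in epithelium or in the other gland lymphocytes than in the spleen group. Calls were also counted on other splits of the same arrays. Figures were drawn with matplotlib 3.10.9.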

Results

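The arrays profiled cells sorted from male NOD mice, a strain used as a model of Sjögren's syndrome, in which lymphocytes infiltrate the lacrimal gland. From the gland there were 4 B cell arrays, 4 CD4 T cell arrays and 3 arrays of epithelial cells, and from the spleen 3 B cell and 3 CD4 T cell arrays. The labels name the spleen subsets as a steady-state control, so the gland against spleen comparisons ask how lymphocytes in the inflamed gland differ from those outside it. Gland donors were 16 weeks old; spleen donors are given as 16 weeks in the sample labels and as 4 weeks in the design text, so tissue and age may or may not differ together. The gland suspension was made with enzymatic digestion, and no such step is stated for the spleen. Nothing in the labels says that replicates came from separate animals, so the p-values below measure only the spread between these samples, which may be technical.

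Lineage genes followed the sort labels. Ms4a1, which encodes the B cell surface protein CD20, had a mean log2 level of 11.08 ± 0.05 (SD) in gland B cells and 11.27 ± 0.10 in spleen B cells, against 4.18 ± 0.92 in gland and 3.40 ± 0.19 in spleen CD4 T cells. Cd3e, a chain of the T cell receptor complex, stood at 9.96 ± 0.11 and 9.89 ± 0.10 in gland and spleen CD4 T cells and at 5.58 ± 0.37 and 4.93 ± 0.79 in the B cells, and Cd4 at 10.67 ± 0.09 and 10.48 ± 0.21 in CD4 T cells and at 5.35 ± 0.54 and 4.8 ± 0.24 in B cells. Epcam, the CD326 antigen of the epithelial gate, stood at 10.68 ± 0.19 in epithelium. Ptprc, which encodes the leukocyte antigen CD45, averaged 10.78 to 10.94 in the 4 lymphocyte groups; in the epithelial sort, gated as negative for CD45, it averaged 4.80 ± 4.17, because replicate 1 stood at 9.61 and the other replicates at 2.38 and 2.40. The Y-linked genes Eif2s3y and Kdm5d had group means of 9.26 to 10.19 and 6.98 to 7.94, and Xist, expressed from an inactive X chromosome, 3.01 to 4.46.

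**Figure D1:**
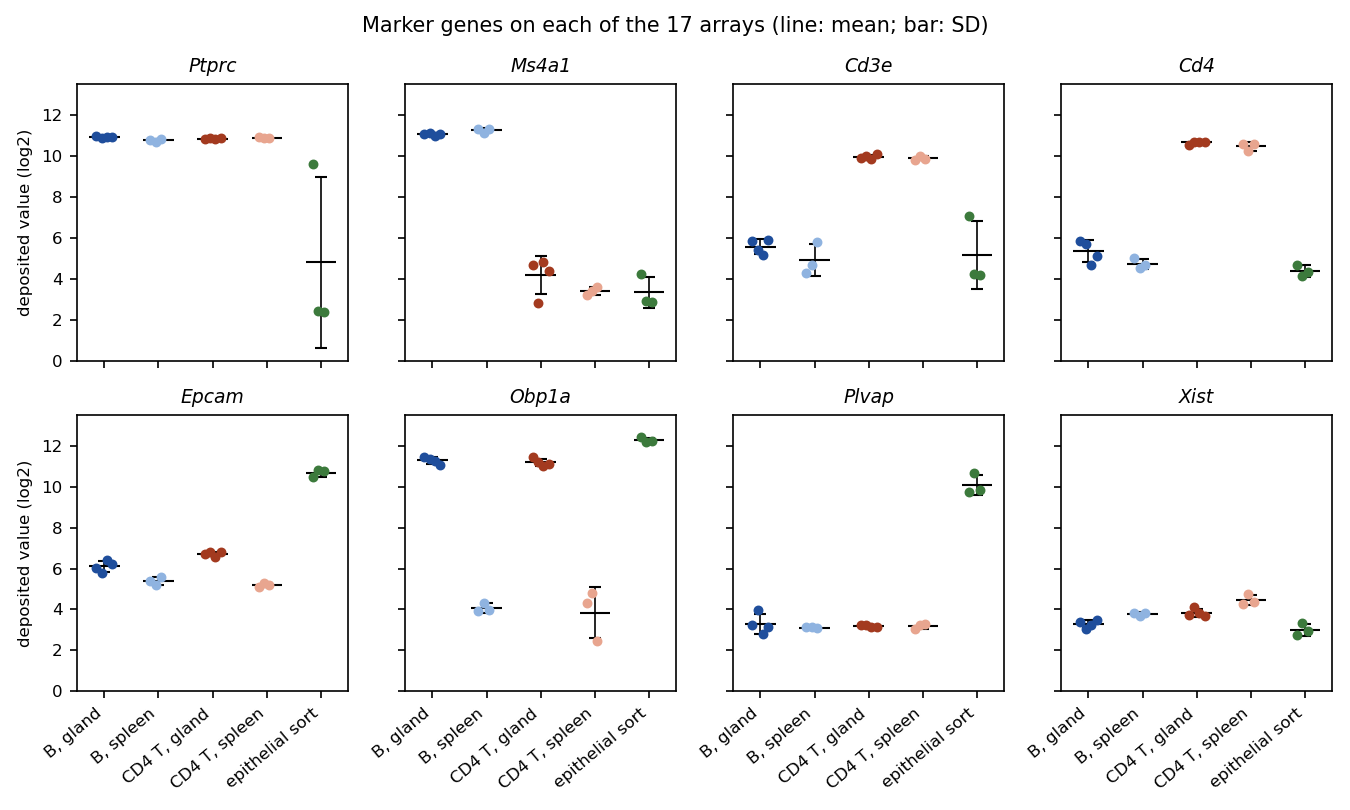
Log2 level (deposited values) of lineage, secretory, endothelial and sex-linked genes in each of the 17 arrays, grouped by sort; each point is an array. Ptprc stands at 9.61 in replicate 1 of the epithelial sort and at 2.38 and 2.40 in the others, and the secretory gene Obp1a is high in gland B and CD4 T cells as well as in epithelium.

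B cells from the gland carried high levels of immediate early genes, interferon-induced genes and gland secretory genes, and low levels of genes of immature and marginal zone B cells. Fosb, a subunit of the AP-1 transcription factor, stood at 10.79 ± 0.11 (SD, n = 4) in gland and 3.96 ± 0.41 (n = 3) in spleen B cells, a 114-fold difference, and Nr4a1, a nuclear receptor induced by antigen receptor signals, at 9.99 ± 0.26 and 5.66 ± 0.13, a 20.1-fold difference. Iigp1, an interferon-inducible GTPase, was 14.6-fold higher in the gland (6.45 ± 0.30 and 2.58 ± 0.50). The values carry no detection calls, so a fold against a level below the median of all values (4.71), as for Fosb and Iigp1 in spleen, is a ratio of deposited values and not of expression shown to be above background. Sox4 and Myb, transcription factors of lymphocyte precursors, fell by 3.44 (SE 0.25) and 2.89 (SE 0.16) on the log2 scale. In all, 441 of 17097 genes were higher and 273 lower in gland than in spleen B cells, and 17 of 43 gene lists shifted, 6 of them also with an estimated correlation. With the adjusted p alone, and separately without genes at least 4-fold higher in gland CD4 T cells than in spleen B cells, more genes were lower than higher (1332 higher and 1687 lower, and 231 and 272).

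Immediate early genes are switched on within a short time of stimulation, stress or cell handling. In B cells 17 of the 22 measured members of that list rose (17 when adjusted over the list alone), with a median log2 fold change of 2.31 (adjusted p = 8.11e-35, and 0.000979 with an estimated correlation). Fosb (adjusted p = 1.09e-13), Fos (49.3-fold), Nr4a2 (30-fold) and Nr4a1 led it. Epithelium from digested glands had a mean level of 9.60 over this list, beside 9.37 in gland B cells and 6.75 in spleen B cells.

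Of the 21 measured genes of the type I interferon list, 17 rose (17 adjusted over the list alone), with a median of 1.72 (adjusted p = 7.33e-14, but adjusted p = 0.22 with an estimated correlation). Oas3, an antiviral RNA sensor, rose 6.78-fold, Usp18, a brake on interferon receptor signalling, 6.55-fold, and Ifit1, which binds viral RNA, 5.98-fold. The list's mean level was 8.46, 8.39, 6.71 and 7.62 in the 4 gland B cell arrays and 5.87 to 6.24 in the spleen arrays. Plasmacytoid dendritic cell genes had mean levels of 7.67, 7.53, 6.65 and 7.14 in the same gland arrays, and 6.58 to 6.62 in spleen. Of 15 measured interferon gamma response genes 10 rose (10 adjusted over the list alone). The median was 1.08 (adjusted p = 4.11e-13, and 0.00351 with an estimated correlation). Among the risen genes were Iigp1, Tgtp1 (5.63-fold) and the chemokine gene Cxcl9 (3.79-fold). Genes of MHC class I presentation had a median of 0.31 (adjusted p = 0.00013, but adjusted p = 0.22 with an estimated correlation), and Nlrc5, the activator of class I genes, was the only called member of 11 (1 adjusted over the list alone), at 2.64-fold. None of the 12 MHC class II genes was called by limma, or reached an unadjusted p under 0.05 (0 genes; list adjusted p = 0.681, and 0.83 by fry).

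Among B cell subset genes, 6 of the 10 measured genes of immature B cells fell (6 adjusted over the list alone). The list had a median of -1.39 (adjusted p = 7.73e-06, and 0.00351 with an estimated correlation), with Vpreb3, made in B cell precursors, at -1.62 and Cd93 at -1.51 beside Sox4 and Myb. With the mean of a gene's probe sets Cd93 was at -0.56 and was no longer called. Marginal zone B cell genes fell in 5 of 9 (5 adjusted over the list alone). Their median was -1.07 (adjusted p = 4.91e-08, and 0.00319 with an estimated correlation). S1pr3, a sphingosine phosphate receptor, fell by 2.15, Dtx1, a Notch target, by 2.02, and Cd1d1, which presents lipids, by 1.44. Cell division genes fell in 12 of 28 (12 adjusted over the list alone). The members had a median of -0.85 (adjusted p = 4.63e-10, but adjusted p = 0.0808 with an estimated correlation), with Nusap1 at -1.77 and Mki67 at -1.56. Nusap1 was at -0.87 with the mean of its probe sets and was no longer called. Red cell precursor genes had a mean level of 4.71 ± 0.28 in gland and 5.67 ± 0.20 in spleen B cells, with 1 of 4 called lower, Hba-a1 (1 adjusted over the list alone). In CD4 T cells it was 4.56 ± 0.26 and 5.67 ± 0.14, with 2 of 4 called lower, Hba-a1 and Alas2 (2 adjusted over the list alone). Alas2 (-1.03) was no longer called without gland replicate 1 (-0.97) or 2 (-0.97), without spleen replicate 3 (-0.999) or with array weights (-0.99). Among the 10 largest decreases over all genes that the naming rule took were, besides Sox4 and Myb, Tsga13 (-4.72), Ffar2, a receptor for short-chain fatty acids (-4.28), Wfdc21 (-3.61) and the chemokine-scavenging receptors Ackr2 (-3.28) and Ackr3 (-2.99). No B cell identity shift passed (adjusted p = 0.285; 1 of 14 genes, Vpreb3, lower; 1 adjusted over the list alone), and germinal centre genes (2 higher, 1 lower of 12; 3 and 1 adjusted over the list alone; adjusted p = 0.436) and plasma cell genes (1 lower of 14, Tnfrsf17; 1 adjusted over the list alone; adjusted p = 0.0663) did not pass either. Tnfrsf17 was at -0.998 and no longer called without spleen replicate 1. Genes of memory and age-associated B cells rose in 2 of 12, Cxcr3 and Cd86 (2.08-fold; 2 adjusted over the list alone; adjusted p = 0.0122, but adjusted p = 0.262 with an estimated correlation, and 0.0143 by fry). Cd86 was at 0.78 and no longer called with probe sets averaged, and was lost without spleen replicate 1 (0.95) or 2 (1.09). Naive follicular B cell genes had 1 of 11 called higher, Klf2 (1 adjusted over the list alone; list adjusted p = 0.0836, and 0.00978 by fry). For germinal centre genes the median was -0.01 while the mean was 0.09 and the test pointed up.

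Some smaller B cell shifts passed with the preset correlation and by fry, but not with an estimated correlation. NF-kB targets rose in 3 of 18 (Nfkbid, Tnfaip3 and Rel; adjusted p = 0.00205, but adjusted p = 0.362 with an estimated correlation). The tissue residency list rose in 3 of 11, with Rgs1, which damps chemokine signals, 22.2-fold higher (adjusted p = 0.0122, but adjusted p = 0.366 with an estimated correlation). Chemokine genes rose in 6 of 27 (adjusted p = 0.00118, but adjusted p = 0.0639 with an estimated correlation). They included Cxcl13, the attractant of B cells to follicles, at 6.30-fold, and Ccl9 and Ccl28, at 7.62-fold and 5.96-fold. Adjusted over the list alone, these 3 lists kept counts of 3, 3 and 6, and by fry their adjusted p was 0.0187, 0.0029 and 0.000263. Nfkbid had an adjusted p = 0.0579 and 0.06 without spleen replicates 1 and 3. Cxcr3, the receptor for Cxcl9, was 3.97-fold higher in gland B cells (adjusted p = 0.0312), and missed the threshold on leaving out any of 6 of the 7 arrays: adjusted p = 0.0607, 0.0614 and 0.0642 without gland replicates 1, 2 and 4, and 0.0926, 0.0525 and 0.107 without spleen replicates 1, 2 and 3.

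Epithelial genes stood high in the same gland B cell arrays. Secretory genes of the lacrimal gland rose in 9 of 15 (9 adjusted over the list alone). The list median was 1.96 (adjusted p = 5.77e-08, and 0.00671 with an estimated correlation). Epithelial identity genes rose in 7 and fell in 1 of 15 (7 and 1 adjusted over the list alone). Their median stood at 0.70 (adjusted p = 2.72e-09, and 0.0272 with an estimated correlation). The odorant-binding protein gene Obp1a stood at 11.29 ± 0.18 in gland B cells, 4.06 ± 0.23 in spleen B cells and 12.28 ± 0.12 in epithelium, and the keratin gene Krt18 at 8.53 ± 0.23, 4.25 ± 0.09 and 12.06 ± 0.12. Prom1, the epithelial gene that fell, stood at 3.60 ± 0.48 in gland and 5.74 ± 0.21 in spleen B cells. None of the 10 endothelial, 11 fibroblast, 15 T cell identity, 14 myeloid and 7 natural killer genes was called by limma in B cells (1, 4, 2, 1 and 0 at an unadjusted p under 0.05), and none of these lists passed by fry. Among T cell subset lists, effector memory genes rose in 4 of 22 (Cxcr3, Id2, Anxa2 and S100a6; 4 adjusted over the list alone; adjusted p = 0.00205, but adjusted p = 0.395 with an estimated correlation). Naive T cell genes rose in 2 of 12 (Ccr9 and Klf2; 2 adjusted over the list alone; adjusted p = 0.0146, but adjusted p = 0.262 with an estimated correlation). Of 16 regulatory T cell genes 3 were called higher (Nrp1, Ctla4 and Il10; 3 adjusted over the list alone; list adjusted p = 0.0829, and 0.00249 by fry). Nrp1 was at 0.96 with the mean of its probe sets, and S100a6 at 0.86 without gland replicate 1, at 0.79 without spleen replicate 2 and at an adjusted p = 0.0504 in a fit of the B cell arrays alone, where neither was called. In 4 lists of markers of other cells 1 gene each was called higher. They were Cd8a, of 2 CD8 T cell genes (2.77-fold), Ccr9, of 5 plasmacytoid dendritic cell genes (4.37-fold), the lactoferrin gene Ltf, of 9 neutrophil genes (12.0-fold), and Mylk, of 8 myoepithelial genes (3.15-fold). Cd8a and Mylk were at 0.90 and 0.61 with the mean of their probe sets and Ccr9 had an adjusted p = 0.0576 in a fit of the B cell arrays alone, which ended these calls. Adjusted over the list alone, 1 gene was higher in each of these 4 lists, and 2 neutrophil genes were lower. The plasmacytoid dendritic cell list did not pass (adjusted p = 0.117) but passed by fry (adjusted p = 0.0201), as did the myoepithelial list (adjusted p = 0.0829, and 0.02 by fry), while the neutrophil list passed by neither (adjusted p = 0.192, and 0.253 by fry). Without the genes at least 4-fold higher in epithelium than in spleen B cells, 177 genes were higher and 262 lower, so that 40.3% of 439 called genes were higher in the gland, against 61.8% with them. On that reduced set the type I interferon (adjusted p = 1.62e-10) and immediate early (adjusted p = 4.36e-13) lists passed at the preset correlation, with medians of 1.33 over 13 genes and 1.03 over 10 genes. The chemokine (adjusted p = 0.0617) and effector memory (adjusted p = 0.0775) lists did not. Of the 9 neutrophil genes 8 were left on that set, with a median of -0.71 (list adjusted p = 0.0718). Over all genes the type I interferon list had an adjusted p = 0.22 with an estimated correlation.

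CD4 T cells from the gland carried high levels of genes of regulatory, effector and helper T cells. Il10, an anti-inflammatory cytokine, stood at 9.34 ± 0.10 (n = 4) in gland and 2.37 ± 0.36 (n = 3) in spleen CD4 T cells, a 126-fold difference of deposited values, with a spleen level not shown to be above background. The chemokine receptor Ccr8 was 32.8-fold higher (8.84 ± 0.22 and 3.80 ± 0.26), the inhibitory receptor Lag3 18.5-fold (9.10 ± 0.06 and 4.90 ± 0.20), and Il21, which helps B cells, 18.2-fold (7.89 ± 0.27 and 3.71 ± 0.42). Ifng, the effector cytokine of Th1 cells, stood at 10.48 ± 0.12 and 5.58 ± 0.43, and Bhlhe40, a transcription factor of cytokine-producing T cells, at 10.90 ± 0.30 and 5.75 ± 0.17. In all, 914 of 17097 genes were higher and 277 lower in gland than in spleen CD4 T cells, and 28 of 43 gene lists shifted, 14 of them also with an estimated correlation.

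Regulatory T cell genes rose in 10 and fell in 1 of 16 (10 and 1 adjusted over the list alone). The median of the list was 1.76 (adjusted p = 7.97e-13, and 0.000983 with an estimated correlation). Besides Il10 they included Ctla4, which competes for costimulatory ligands (9.83-fold), Itgae, an integrin of lymphocytes in epithelia (5.79-fold), and Tnfrsf4, the costimulatory receptor OX40 (5.43-fold). Foxp3, the lineage factor of regulatory T cells, chosen after its values were seen, stood at 9.68 ± 0.17 in the gland and 8.35 ± 0.12 in the spleen, a 2.50-fold rise (adjusted p = 1.38e-07). Inhibitory receptor genes rose in 6 and fell in 1 of 9 (6 and 1 adjusted over the list alone). Their median difference was 1.90 (adjusted p = 1.81e-06, and 0.0341 with an estimated correlation), with Pdcd1 at 7.24-fold and Havcr2 at 5.84-fold. Follicular helper genes rose in 7 of 14 (7 adjusted over the list alone). Across the list the median was 1.20 (adjusted p = 2.14e-08, and 0.014 with an estimated correlation), with Cxcl13 at 12.2-fold and the transcription factor Maf at 7.63-fold beside Il21.

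Th1 genes rose in 7 of 13 (8 adjusted over the list alone). The median was 1.87 (adjusted p = 0.000271, but adjusted p = 0.286 with an estimated correlation). Effector memory genes rose in 12 of 22 (15 adjusted over the list alone). The list had a median of 1.27 (adjusted p = 2.12e-07, but adjusted p = 0.105 with an estimated correlation). The genes of these lists included Ccl5 (8.55-fold), the granzyme gene Gzmk (6.57-fold) and Prdm1, a factor of terminal differentiation (5.02-fold). Tbx21, the lineage factor of Th1 cells, was 5.91-fold higher (adjusted p = 0.0256), with adjusted p = 0.0514 without gland replicate 3 and 0.0929 and 0.0651 without spleen replicates 1 and 3. Tissue residency genes rose in 7 of 11 (7 adjusted over the list alone). Their median was 2.33 (adjusted p = 7.12e-07, and 0.0457 with an estimated correlation), led by Bhlhe40 and Rgs2 (13.2-fold). Genes of naive T cells fell in 3 and rose in 1 of 12 (3 and 1 adjusted over the list alone). The members had a median of -0.51 (adjusted p = 0.00667, but adjusted p = 0.13 with an estimated correlation). The gut-homing receptor gene Ccr9 fell by 2.32, the transcription factor gene Lef1 by 1.42 and Actn1 by 1.12, while the growth factor receptor gene Igf1r rose by 1.76.

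Signalling and cytokine groups rose too. NF-kB targets rose in 10 of 18 (12 adjusted over the list alone). The list median was 1.22 (adjusted p = 5.54e-12, and 0.0259 with an estimated correlation), with the inhibitors Tnfaip3 at 10.3-fold and Nfkbia at 3.77-fold. Immediate early genes rose in 15 of 22 (15 adjusted over the list alone). Their median stood at 2.23 (adjusted p = 3.23e-22, and 0.00388 with an estimated correlation), with Fosb at 77.3-fold, Jun at 30.8-fold and the heat shock gene Hspa1b at 31.0-fold. The mean level over this list was 9.26 in gland and 6.87 in spleen CD4 T cells, beside 9.60 in epithelium from digested glands. Whether the digestion raised these genes was not tested. Chemokine genes rose in 12 of 27 (12 adjusted over the list alone). The median of the list was 0.47 (adjusted p = 1.33e-07, and 0.00778 with an estimated correlation), with Ccl3 at 48.9-fold and Cxcl10, a ligand of the receptor Cxcr3, at 18.6-fold. Genes of the TNF family rose in 6 of 17 (6 adjusted over the list alone; adjusted p = 0.000317, and 0.0341 with an estimated correlation), among them Tnfsf11, which encodes RANKL (4.80-fold), and Tnf (2.61-fold). Glycolysis genes rose in 3 of 12 (3 adjusted over the list alone). Their median difference was 0.46 (adjusted p = 1.98e-07, and 0.0457 with an estimated correlation), with Hk2 at 3.14-fold and Tpi1 at 2.89-fold. Type I interferon genes rose in 14 of 21 (14 adjusted over the list alone). Across the list the median was 1.5 (adjusted p = 2.14e-08, but adjusted p = 0.237 with an estimated correlation), with the antiviral genes Mx1 at 13.6-fold and Rsad2 at 7.58-fold. Interferon gamma response genes rose in 5 of 15 (5 adjusted over the list alone). The median was 0.60 (adjusted p = 3.23e-07, and 0.0259 with an estimated correlation).

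Genes usually tied to other cells also stood higher in gland than in spleen CD4 T cells. MHC class II genes rose in 6 and fell in 1 of 12 (6 and 1 adjusted over the list alone). The list had a median of 0.97 (adjusted p = 0.00436, but adjusted p = 0.359 with an estimated correlation). H2-Aa stood at 7.54 ± 0.17 in gland and 4.83 ± 0.27 in spleen CD4 T cells, beside 11.84 ± 0.05 in gland B cells. Macrophage and monocyte genes had 1 of 14 called higher (Cd14, 2.68-fold; 1 adjusted over the list alone), and their list rose (adjusted p = 0.0091, but adjusted p = 0.359 with an estimated correlation), from a mean level of 4.86 ± 0.22 in spleen to 5.56 ± 0.02. Of 9 neutrophil genes 2 were called higher, Ltf (50.3-fold) and Mmp9 (2.36-fold; 2 adjusted over the list alone; list adjusted p = 0.47). Without genes at least 4-fold higher in epithelium than in spleen CD4 T cells, 8 were left (median -0.05, list adjusted p = 0.668). Mmp9 was at 0.98 with the mean of its probe sets and was no longer called. Plasma cell genes rose in 5 of 14 (5 adjusted over the list alone). Their median was 0.57 (adjusted p = 0.000648, but adjusted p = 0.16 with an estimated correlation), with Jchain, the joining chain of secreted antibodies, at 9.09 ± 0.53 and 5.57 ± 1.30. The others included Prdm1 and Irf4, which activated T cells also express. Of the B cell identity genes, 1 of 14 rose (Bank1, 2.70-fold; 1 adjusted over the list alone; list adjusted p = 0.0795), and 3 of 15 immunoglobulin gene segments rose. Secretory genes rose in 10 of 15 (10 adjusted over the list alone). The members had a median of 2.18 (adjusted p = 7.12e-07, and 0.0141 with an estimated correlation). Epithelial identity genes rose in 8 of 15 (8 adjusted over the list alone). The list median was 1.5 (adjusted p = 4.47e-10, and 0.0197 with an estimated correlation). Obp1a stood at 11.19 ± 0.18 in gland and 3.85 ± 1.24 in spleen CD4 T cells. Without the genes at least 4-fold higher in epithelium than in spleen CD4 T cells, 476 genes were higher and 268 lower, 744 in all. On that reduced set regulatory T cell (adjusted p = 1.28e-14), NF-kB (adjusted p = 9.68e-15), follicular helper (adjusted p = 3.4e-10) and inhibitory receptor (adjusted p = 6.66e-08) lists still passed.

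**Figure D2:**
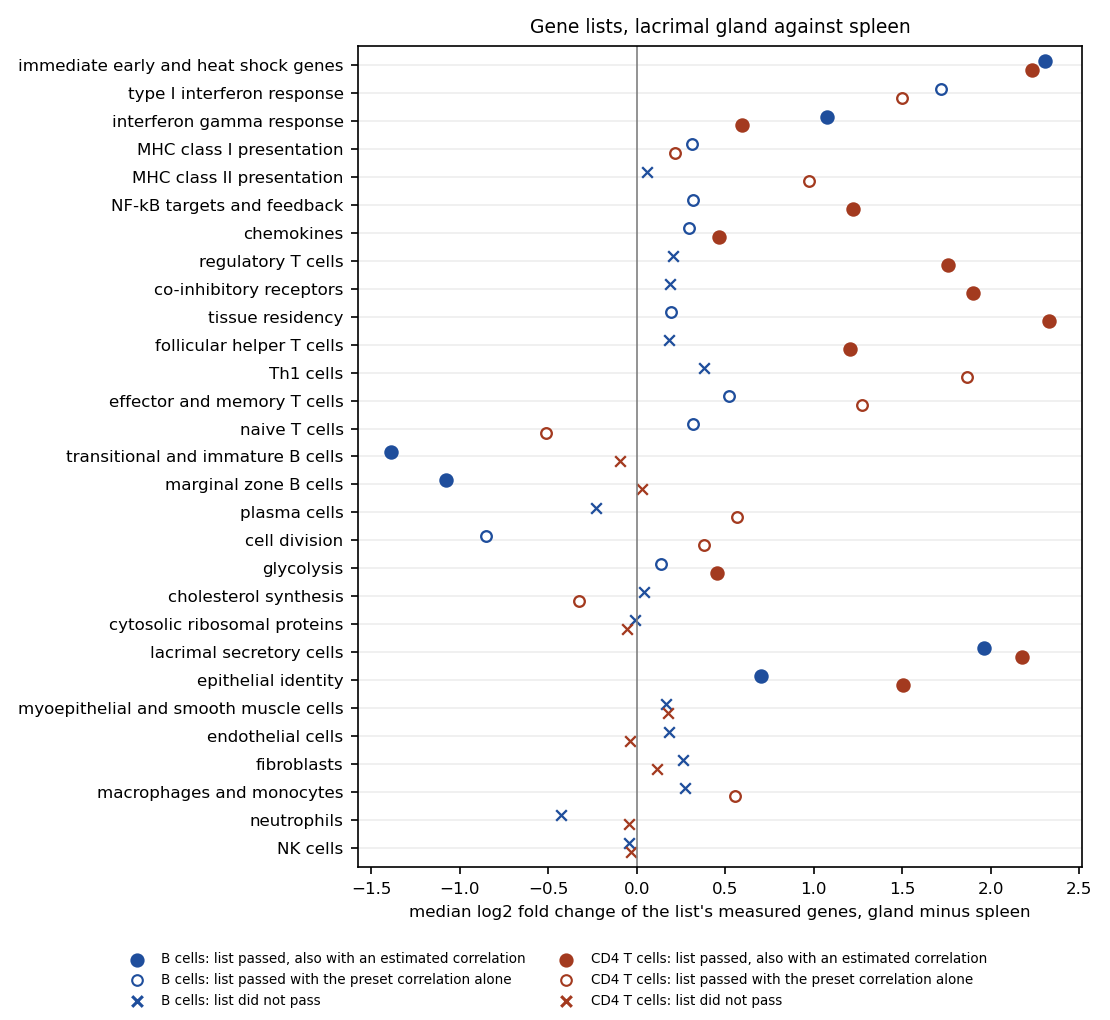
Median log2 fold change, gland minus spleen, of each gene list in B cells and in CD4 T cells; filled points passed the list test with the preset and with the estimated correlation, open points with the preset alone, and crosses did not pass. Regulatory T cell genes have a median of 1.76 in CD4 T cells and 0.20 in B cells, and immediate early genes 2.23 and 2.31.

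The gland against spleen changes of B and CD4 T cells overlapped. Across 17097 genes the changes had a Pearson r of 0.554 and a Spearman rho of 0.407; genes are not independent replicates, so no p is given. Higher in the gland in both subsets were 277 genes, against 23.6 if the sets were independent, and lower in both were 60, against 4.42; 20 genes went opposite ways. Of the 277, 172 stood at least 4-fold higher in epithelium than in both spleen groups, among them Obp1a, Pip and Krt18. Without the genes at least 4-fold higher in epithelium than in either spleen group r was 0.395 over 15195 genes. Fosb, Nr4a2 and the interferon-induced gene Oasl2 were among the genes higher in both subsets, and Sox4, Dtx1 and the haemoglobin gene Hba-a1 among those lower in both.

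**Figure D3:**
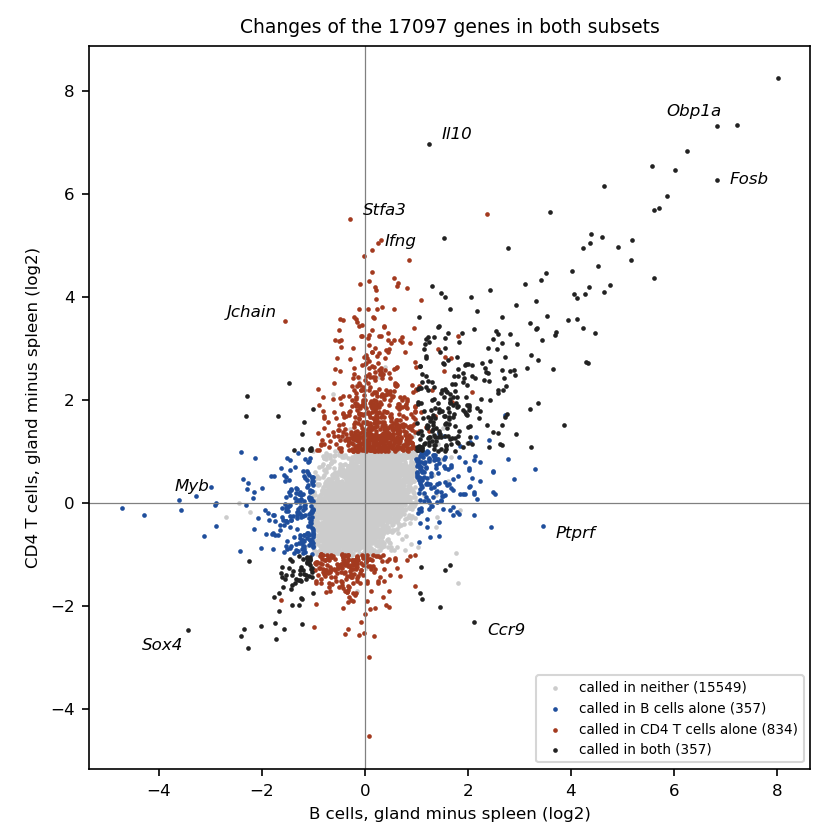
Log2 fold change, gland minus spleen, in B cells (x axis) against that in CD4 T cells (y axis); each point is a gene, coloured by the subset in which it was called. Obp1a and Fosb lie high on both axes, and Il10 (1.24 and 6.97) and Ifng lie high on the CD4 T cell axis.

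The change from spleen to gland differed between B and CD4 T cells in 869 of 17097 genes, and in 661 of them it was lower in B cells; of 43 lists 26 shifted, 11 of them also with an estimated correlation. The difference of the changes, B minus CD4 T, was -5.74 (SE 0.28) for Il10, -4.77 (SE 0.18) for Ccr8, -3.98 for Il21 and -3.59 for Lag3. Stfa3, which encodes a stefin, an inhibitor of cysteine proteases, had the largest negative difference that the naming rule took (-5.80, SE 0.56): it stood at 11.29 ± 0.07 in gland and 5.77 ± 0.52 in spleen CD4 T cells, and at 3.66 ± 0.21 and 3.95 ± 0.59 in the B cells. Ccr9 had the largest positive one (4.45, SE 0.70): it stood at 7.66 ± 1.36 in gland and 5.53 ± 0.30 in spleen B cells, and at 5.09 ± 0.29 and 7.41 ± 0.29 in CD4 T cells.

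Grouped by list, the change of regulatory T cell genes was lower in B cells in 11 and higher in 1 of 16 (11 and 1 adjusted over the list alone). Their median stood at -1.61 (adjusted p = 5.75e-11, and 0.00209 with an estimated correlation). The list had mean levels of 5.24 in gland and 4.97 in spleen B cells and of 9.47 and 7.68 in CD4 T cells. That of inhibitory receptor genes was lower in 6 of 9 (6 adjusted over the list alone, with 1 higher), with a median of -1.68 (adjusted p = 2.33e-06, and 0.0292 with an estimated correlation). That of follicular helper genes was lower in 6 of 14 (6 adjusted over the list alone; adjusted p = 5.73e-07, and 0.0163 with an estimated correlation). Cell division genes differed in 17 of 28 (17 adjusted over the list alone). The median of the list was -1.28 (adjusted p = 9.37e-15, and 0.0222 with an estimated correlation). The difference was -2.38 for the spindle checkpoint kinase Bub1 and -2.28 for Nusap1, which stood at 5.24 ± 0.56 in gland and 7.0 ± 0.30 in spleen B cells and at 7.55 ± 0.28 and 7.04 ± 0.21 in CD4 T cells. Immature B cell genes were lower in 5 of 10 (5 adjusted over the list alone). Their median difference was -1.19 (adjusted p = 4.33e-05, and 0.0124 with an estimated correlation), with Myb at -2.87. Marginal zone genes were lower in 4 of 9 (4 adjusted over the list alone). Across the list the median was -0.87 (adjusted p = 7.46e-05, and 0.0163 with an estimated correlation), with S1pr3 at -2.35. In CD4 T cells of gland and spleen the mean levels were 4.84 and 5.0 for immature B cell genes and 5.44 and 5.66 for marginal zone genes. Naive T cell genes were higher in 7 and lower in 1 of 12 (7 and 1 adjusted over the list alone). The median was 1.1 (adjusted p = 8e-06, and 0.0237 with an estimated correlation). Ccr9 and Klf2, a factor of recirculating lymphocytes (1.82), were among the higher genes.

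For interferon genes the subsets differed in single members. No type I interferon gene of 21 was called by limma for a difference in change, with 8 at an unadjusted p under 0.05 (0 adjusted over the list alone; list median 0.41, adjusted p = 0.215, and 0.624 by fry), and the gland against spleen medians were 1.72 in B and 1.5 in CD4 T cells. Interferon gamma response genes split, 2 higher and 2 lower of 15 (2 and 2 adjusted over the list alone). The list had a median of 0.37 (adjusted p = 0.0264, but adjusted p = 0.276 with an estimated correlation). Iigp1 (2.36) and Tgtp1 (2.28) changed more in B cells, and Cxcl10 (-2.92) and Gbp3 (-1.99) more in CD4 T cells. Among immediate early genes 4 were higher and 2 lower of 22 (4 and 2 adjusted over the list alone). Their median was 0.32 (adjusted p = 0.00539, but adjusted p = 0.276 with an estimated correlation), with Nr4a1 at 1.61 and Jun at -2.17. No secretory gene of 15 was called by limma for a difference between the subsets or reached an unadjusted p under 0.05 (list adjusted p = 0.68, and 0.562 by fry). The difference for Ifng (-4.78, adjusted p = 0.0317) missed the threshold without any of 10 of the 14 arrays: adjusted p = 0.0556 and 0.0547 without gland B cell replicates 2 and 3, 0.0746 and 0.0763 without spleen B cell replicates 2 and 3, 0.0518, 0.0564 and 0.0521 without gland CD4 T cell replicates 1, 3 and 4, and 0.0771, 0.0589 and 0.0552 without spleen CD4 T cell replicates 1, 2 and 3.

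**Figure D4:**
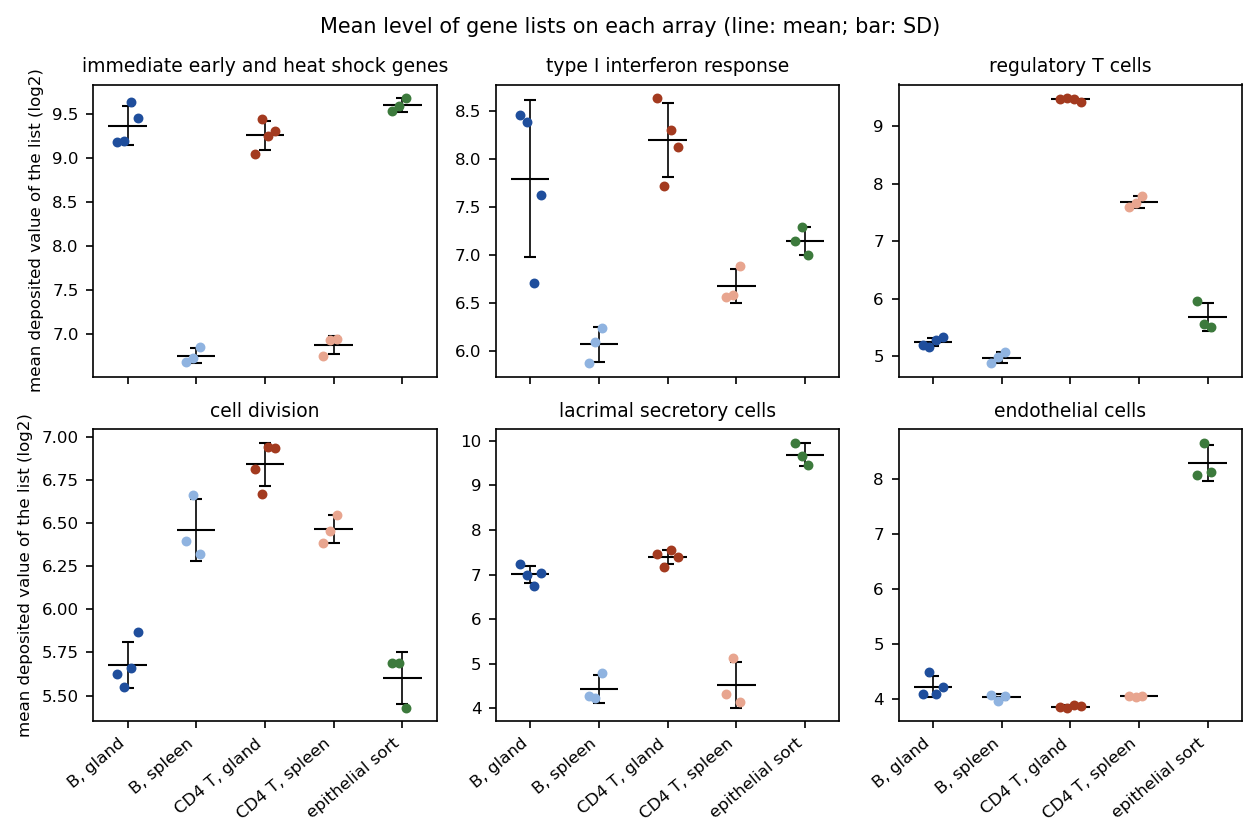
Mean log2 level of 6 gene lists in each of the 17 arrays, by sort; points are arrays, lines are group means and bars are SD. Type I interferon genes range from 6.71 to 8.46 in gland B cells, and cell division genes average 5.68 in gland and 6.46 in spleen B cells.

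The epithelial sort differed from the gland lymphocytes in 4299 of 17097 genes, 2540 higher and 1759 lower than the mean of gland B and CD4 T cells; the median of all genes was -0.10. With the adjusted p alone 4569 genes were higher and 6313 lower. All 15 measured epithelial identity genes were higher, among them the tight junction gene Cldn7 (29.5-fold; 10.19 ± 0.35, n = 3, against 5.11 ± 0.47 in B and 5.51 ± 0.58 in CD4 T cells, n = 4 each) and the keratin gene Krt7 (24.5-fold), with a list median of 4.08. Secretory genes were higher in 12 of 15 (12 adjusted over the list alone). The members had a median of 2.63 (adjusted p = 7.23e-05, but adjusted p = 0.0605 with an estimated correlation). Among the higher genes were the water channel gene Aqp5 (13.4-fold) and the carbonic anhydrase gene Car6 (12.5-fold). Myoepithelial genes, of the contractile cells around the acini, were higher in 7 of 8 (7 adjusted over the list alone). The list median was 2.78 (adjusted p = 7.23e-05, but adjusted p = 0.0605 with an estimated correlation), with Acta2 at 82.1-fold and Krt14 at 54.0-fold.

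Among the 20 largest increases that the naming rule took were Cavin2 (195-fold), the angiopoietin receptor gene Tek (169-fold), the caveolin gene Cav1 (160-fold), the VEGF receptor gene Flt1 (149-fold) and the basement membrane collagens Col4a2 (142-fold) and Col4a1 (133-fold). Cavin2 averaged 2.73 in gland B and 2.47 in gland CD4 T cells, and a fold against such dim levels is a ratio of deposited values. Endothelial markers were higher in 9 of 10 (9 adjusted over the list alone). Their median stood at 4.34 (adjusted p = 3e-07, but adjusted p = 0.101 with an estimated correlation), with Plvap at 10.07 ± 0.50 in the epithelial sort and 3.30 ± 0.49 and 3.20 ± 0.04 in gland B and CD4 T cells. Fibroblast markers were higher in 8 of 11 (8 adjusted over the list alone). The median of the list was 3.75 (adjusted p = 4.64e-07, but adjusted p = 0.0605 with an estimated correlation), and Col3a1 (60.3-fold) and Postn (48.4-fold) were among the higher genes.

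Signalling genes of the epithelial sort included the neutrophil attractants Cxcl1 (45.1-fold) and Cxcl2 (26.4-fold), the mucosal chemokine gene Ccl28 (19.3-fold), the alarmin gene Il33 (33.2-fold) and Tnfsf13, which encodes APRIL, a survival factor of B cells and plasma cells (16.4-fold). Chemokine genes were higher in 8 and lower in 4 of 27 (8 and 4 adjusted over the list alone). Their median difference was 0.16 (adjusted p = 0.0468, but adjusted p = 0.228 with an estimated correlation). Lower than the mean of gland B and CD4 T cells were the transcription factor gene Irf4 (-6.98), the inhibitory receptor gene Btla (-6.76) and 11 of 12 MHC class II genes (11 adjusted over the list alone). Across the list the median was -3.50 (adjusted p = 0.000103, but adjusted p = 0.259 with an estimated correlation), with H2-Aa at 5.26 ± 2.39. The list's mean level in the epithelial sort was 6.97 in replicate 1 and 4.92 and 5.23 in the others. Lower too than the mean of gland B and CD4 T cells were 14 of 15 T cell identity genes (14 adjusted over the list alone, adjusted p = 2.27e-05, but adjusted p = 0.241 with an estimated correlation). So were 11 of 14 B cell identity genes (11 adjusted over the list alone, adjusted p = 4.85e-05, but adjusted p = 0.11 with an estimated correlation). A call of lower did not need a lower mean than in each subset. T cell identity genes averaged 4.45 in the epithelial sort, 4.69 in gland B and 9.86 in gland CD4 T cells. For B cell identity genes these means were 4.46, 9.95 and 4.80. T cell identity genes averaged 5.68 in replicate 1 of the epithelial sort and 3.82 and 3.85 in the others. Type I interferon genes were higher in 2 and lower in 9 of 21 (2 and 9 adjusted over the list alone). The median was -0.86 (adjusted p = 0.0526). For myeloid (median 0.09, mean -0.25, test up), plasma cell (0.52, -0.52, up), germinal centre (-0.15, 0.23, up), immature B cell (-0.22, 0.72, up) and neutrophil genes (-0.11, 0.11, down) the median, the mean and the test differed in sign, and none of these lists passed.

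With the preset correlation 26 of 43 lists passed in the epithelial comparison; with a correlation estimated per list camera called 0, with 9 at an unadjusted p under 0.05, and fry called 38. The epithelial identity list had an adjusted p = 1.63e-09 (15 genes adjusted over the list alone), but adjusted p = 0.0584 with an estimated correlation.

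Within the gland, 638 genes were higher in B cells and 1021 higher in CD4 T cells, and 18 of 43 lists shifted, 6 of them also with an estimated correlation. B cell identity genes were higher in 13 of 14 (13 adjusted over the list alone). The list had a median of 5.95 (adjusted p = 7.16e-21, and 0.00142 with an estimated correlation), led by the B cell adaptor gene Bank1 (128-fold; 10.73 ± 0.09 against 3.73 ± 0.48, n = 4 each) and Ms4a1 (119-fold). T cell identity genes were lower in 14 of 15 (14 adjusted over the list alone). Their median was -5.49 (adjusted p = 7.94e-20, and 0.0432 with an estimated correlation), with the receptor chain gene Cd3g at -6.77. Stfa3 (-7.63) and Nrn1 (-7.04) had the largest differences toward CD4 T cells that the naming rule took, followed by Tnfsf11 (-6.84).

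B cells also had higher levels of the follicular B cell genes Fcer2a (90.6-fold) and Cr2 (61.8-fold), whose list was higher in 8 of 11 (8 adjusted over the list alone). The members had a median of 1.61 (adjusted p = 1.78e-09, and 0.00142 with an estimated correlation). MHC class II genes were higher in B cells in 11 of 12 (11 adjusted over the list alone). The list median was 4.24 (adjusted p = 3.4e-12, but adjusted p = 0.0857 with an estimated correlation). CD4 T cells had higher levels of 14 of 16 regulatory T cell genes (14 adjusted over the list alone). Their median stood at -4.56 (adjusted p = 2.32e-21, and 6.73e-05 with an estimated correlation), with the Helios gene Ikzf2 at -6.81 and Il10 at -6.07. Effector memory genes were higher in CD4 T cells in 18 of 22 (18 adjusted over the list alone). The median of the list was -3.08 (adjusted p = 3.12e-13, but adjusted p = 0.0543 with an estimated correlation). Cell division genes were higher in CD4 T cells in 14 of 28 (14 adjusted over the list alone). Their median difference was -1.11 (adjusted p = 3.68e-12, but adjusted p = 0.0543 with an estimated correlation), with the thymidylate synthase gene Tyms at -2.55 and Mki67 at -2.08. Tyms was at -0.83 with the mean of its probe sets and was no longer called. Epithelial identity genes did not differ by call (0 of 15 by limma, with 2 at an unadjusted p under 0.05; 0 adjusted over the list alone; list adjusted p = 0.355, and 0.225 by fry), and of the secretory genes 1 of 15, the potassium channel gene Kcnn4, was lower in B cells (1 adjusted over the list alone).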

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

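Of the tests below, those of the endothelial and fibroblast share, of the interferon genes and of the epithelial sort were chosen only after the results were seen; the correlation of the epithelial genes and the counts on other splits of the arrays were planned.

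Secretory and epithelial genes stood higher in gland than in spleen lymphocytes: of 540 genes at least 16-fold higher in epithelium, 165 were called higher in gland B cells and 223 in gland CD4 T cells. Cells of the whole epithelial sort carried into the lymphocyte sorts are argued against, for the endothelial and fibroblast genes called in the epithelial comparison. The upper quartile of their shares of the epithelial-sort level was 1.28% in B and 0.404% in CD4 T cells. The lower quartile of the epithelial identity shares was 1.58% and 2.12%, so the margin in B cells was narrow. Endothelial and fibroblast genes reached at most a median share of 0.869% of their epithelial-sort level. Epithelial identity genes had medians of 2.45% in B and 4.25% in CD4 T cells, and secretory genes 6.01% and 8.39%. The endothelial, fibroblast and secretory genes were those called in the epithelial comparison, which can leave out genes with a high share. Among the endothelial and fibroblast genes kept, the highest share was 3.73% in B and 50.2% in CD4 T cells. RNA or cells of the secretory epithelium carried into these sorts cannot be told apart by the planned test from a change within the lymphocytes. The changes in B and CD4 T cells had a Spearman rho of 0.691 over the 540 genes. This lay between the bounds set for it before the test, over 0.8 for a shared source and under 0.5 for none. The Pearson r over the same genes, for which no bound was set, was higher, at 0.843. The gate on lymphocyte markers would remove whole epithelial cells but not RNA attached to a lymphocyte. The tissue, the digestion stated for the gland alone and, by the design text, the age of the donors differed as well, and all stay open as untested.

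Interferon-stimulated genes stood higher in gland lymphocytes of both subsets, with list medians of 1.72 in B and 1.5 in CD4 T cells, though the list tests did not pass with an estimated correlation (adjusted p = 0.22 in B and adjusted p = 0.237 in CD4 T cells). Carry-over of such RNA from the epithelial sort is argued against: the called genes would need shares of the epithelial level with lower quartiles of 79.2% in B and 194% in CD4 T cells, where epithelial identity genes reached at most 10.7% and 13.8% and secretory genes at most 43.2% and 47.2%; for the single genes with the lowest shares needed, 17.9% and 42.2%, it stays open. Plasmacytoid dendritic cells in the gland B cell sort cannot be told apart from a response of the B cells: of 5 genes of such cells 1 was called higher, Ccr9 (2.13), and the list passed by fry alone (adjusted p = 0.0201, against 0.117), while the gate on B220 without CD11c would not remove every such cell. Array by array these genes had mean levels of 7.67, 7.53, 6.65 and 7.14 and CD8 T cell genes 5.88, 5.68, 4.94 and 4.99, beside 8.46, 8.39, 6.71 and 7.62 for the interferon list; Ccr9 stood at 8.88, 8.54, 5.87 and 7.34, and Tcf4 at 9.15 to 9.34, beside a mean of 9.12 in spleen B cells. A response to interferon within the gland lymphocytes stays open as a hypothesis, as do the tissue, the digestion of the gland and the age of the donors, none of them tested.

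Endothelial, stromal and leukocyte genes stood high in the epithelial sort. Free endothelial and stromal RNA in the gland suspension is argued against as the source of such high levels. In lymphocytes from the same kind of suspension, the pooled endothelial and fibroblast lists had at most a median gland against spleen change of 0.21. Smaller amounts stay open: every gland array stood above every spleen array for fibroblast genes in both subsets and for endothelial genes in B cells. Fibroblast genes averaged 3.56 in gland and 3.34 in spleen B cells, 3.72 and 3.33 in CD4 T cells, and 6.86 in the epithelial sort. Endothelial genes averaged 4.22 and 4.03 in B cells, 3.86 and 4.04 in CD4 T cells, and 8.28 in the epithelial sort. A leukocyte array under the label of replicate 1 is argued against too, since its epithelial identity genes differed from the other replicates by a median of -0.33 only. Endothelial and stromal cells within the sort, which a gate on CD326 should remove, cannot be told apart from other sources: 17 of 21 endothelial and fibroblast genes were called higher, but these are the genes that make up the pattern. Leukocytes in replicate 1, which the gate against CD45 should remove, stay open in the same way: 24 of 36 natural killer, T cell and myeloid genes stood at least 2-fold above each other replicate there, but that replicate was singled out because such genes were high in it. No biological explanation was tested for this pattern.

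Counts on other splits of the same arrays, the real split included, ask whether a chance division of these arrays gave as many calls. They cannot exclude chance differences between animals, since nothing in the labels says that replicates came from separate animals. For called genes a chance division is argued against in B cells, gland against spleen (714 genes, highest of the other splits 293, 1 of 35 splits with as many). The same holds in CD4 T cells (1191 and 642, 1 of 35). The real split also gave the most genes in the epithelial comparison (4299 and 797, 1 of 100) and for B against CD4 T cells of the gland (1659 and 1, 1 of 35). Those groups were sorted by lineage markers, so a large count there was set in advance. For the difference of the changes 3 of 100 splits gave 869 genes or more, with a highest of 2000; in the 2 other splits, with 1589 and 2000 genes, 6 of the 7 arrays of a subset changed places, so that the tissue changes of the subsets added up, which points to a structure of the samples. For gene lists the share of splits with as many was low in the epithelial comparison alone (26 lists, highest other 26, 2 of 100 splits). Even there no list passed with an estimated correlation, and the other split with 26 lists had 2 called genes. The count of lists therefore does not set the real groups apart. In the others a chance division of the arrays is not excluded: 17 against a highest other of 18 in B cells (3 of 35), 28 against 28 in CD4 T cells (3 of 35), 26 against 32 for the difference of the changes (9 of 100) and 18 against 20 within the gland (4 of 35). In B and in CD4 T cells, gland against spleen, the other splits with as many lists changed the places of 6 of the 7 arrays and so held the tissue change with its sign turned, which again points to a structure of the samples.

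In groups of 4 arrays, a single array stood far from the other 3 in 8 of 86 list means and 18 of 254 gene levels tested; chance alone gives about 1 in 20. Among list means of gland B cells, replicate 3 stood apart for MHC class II (10.94), interferon gamma response (6.82, the others at 7.07 to 7.10) and Th17 genes (5.08), and replicate 4 for memory B cell genes (6.41). Among those of gland CD4 T cells, replicate 1 stood apart for immature B cell (4.76) and interleukin genes (4.29), replicate 2 for MHC class I (10.17, the others at 10.35 to 10.38) and replicate 3 for myoepithelial genes (4.56). Single genes with an array apart in gland B cells were Rel (10.23), Prdm1 (5.78), Id2 (7.89), Ahr (7.64) and Col4a1 (5.02) in replicate 3, Vpreb3 (8.37) in replicate 4, Cavin2 (3.24) in replicate 2 and Cd3g (3.69) and Xbp1 (8.37) in replicate 1. In gland CD4 T cells they were Ccl3 (7.45), Rgs2 (10.91), Btla (9.53), Mmp9 (5.87), S100a6 (10.45) and Cxcl1 (3.79) in replicate 2, Havcr2 (5.18) in replicate 4, Cxcl2 (2.65) in replicate 1 and Flt1 (3.65) in replicate 3.

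The gland against spleen change differed between the subsets, by the test of the difference itself, in 869 genes and 26 lists, 11 of them also with an estimated correlation. With it the other 15 had adjusted p = 0.0639 for plasma cell, 0.082 for chemokine, 0.101 for Th2, 0.101 for NF-kB target, 0.101 for tissue residency, 0.179 for glycolysis, 0.238 for B cell identity, 0.276 for interferon gamma response, 0.276 for immediate early, 0.332 for tissue egress, 0.47 for endothelial, 0.47 for unfolded protein response, 0.486 for effector memory, 0.5 for Th1 and 0.5 for MHC class II genes. List medians of the difference, B minus CD4 T, were 1.1 for naive T cell, 0.58 for tissue egress, 0.41 for cholesterol synthesis, 0.37 for interferon gamma response, 0.32 for immediate early and 0.27 for endothelial genes. They were -0.00698 for interleukin, -0.18 for chemokine, -0.21 for unfolded protein response, -0.29 for glycolysis, -0.36 for Th2, -0.52 for B cell identity, -0.67 for effector memory, -0.68 for TNF family, -0.82 for follicular helper, -0.84 for NF-kB target, -0.85 for B-1 cell, -0.85 for MHC class II and -0.87 for marginal zone genes. Further from 0 were plasma cell (-1.08), immature B cell (-1.19), Th1 (-1.04), cell division (-1.28), tissue residency (-1.54), regulatory T cell (-1.61) and inhibitory receptor genes (-1.68). For single genes the difference was 4.45 for Ccr9, 3.91 for Ptprf, 3.48 for Amigo2, 3.09 for Drc1, 2.97 for Trpm1, 2.36 for Iigp1, 2.28 for Tgtp1, 1.82 for Klf2 and 1.61 for Nr4a1. On the other side it was -1.99 for Gbp3, -2.17 for Jun, -2.28 for Nusap1, -2.35 for S1pr3, -2.38 for Bub1, -2.87 for Myb, -2.92 for Cxcl10, -3.59 for Lag3, -3.78 for Il18, -3.98 for Il21, -4.77 for Ccr8, -4.78 for Ifng, -4.80 for Ccn4, -5.07 for Jchain, -5.74 for Il10 and -5.80 for Stfa3.

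Probe sets without a single gene name, which no comparison used, held a signal too. Tested in the same way, gland against spleen, 631 of 16139 were called in B cells, 296 higher and 335 lower. In CD4 T cells 1190 were called, 529 higher and 661 lower. More were thus lower than higher in both subsets, unlike the called genes (441 higher and 273 lower in B cells, 914 and 277 in CD4 T cells).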

How the results depend on the processing

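The fits without the 4 arrays that stand apart (replicate 1 of the epithelial sort, 3 of spleen B cells, 3 of gland B cells and 2 of gland CD4 T cells) and the list tests without genes higher in epithelium were chosen after seeing the data; the other alternatives were planned, and no named gene turned its direction under any of them. Counts of called genes (714 in B cells and 1191 in CD4 T cells, gland against spleen, 869 for the difference of the changes, 4299 in the epithelial comparison and 1659 within the gland) rose to 3019, 3995, 1731, 10882 and 5196 with the adjusted p alone, because no fold change was required. Without genes higher in epithelium they were 439 in B and 744 in CD4 T cells, with fewer genes tested. They stayed within 1.5 times under every other setting: leaving out each array gave 642 to 746, 1128 to 1228, 800 to 886, 4263 to 4418 and 1631 to 1694, and leaving out the 4 arrays that stand apart 727, 1172, 959, 4448 and 1694. With the replicate number as a replicate block the counts were 730, 1215, 840, 4276 and 1652. Arrays with the same number mostly did not deviate together (r from -0.15 to -0.0268 over 3 pairs of gland and spleen B cell arrays, -0.131 to -0.0452 in CD4 T cells, -0.493 to 0.221 over 4 pairs within the gland). The highest r of any such pair was 0.229, for replicate 1 of gland B and spleen CD4 T cells. The numbers were not taken as pairs, though the labels leave this open. With an estimated correlation, the lists that passed went from 17, 28, 26, 26 and 18 to 6, 14, 11, 0 and 6, and with fry from 18 to 30 within the gland; the cause was not tested. Leaving out each array gave 16 to 19, 28 to 30, 24 to 31, 24 to 27 and 18 to 19 lists. Without genes higher in epithelium 14 lists passed in B and 27 in CD4 T cells. The correlation of the changes of B and CD4 T cells, 0.554, was 0.574 with a filter on dim probes, 0.395 without genes higher in epithelium, and 0.538 to 0.560 on leaving out each array; the cause was not tested. Of the named called genes, those called under every setting that tested them were 65 of 83, 94 of 108, 74 of 89, 140 of 156 and 109 of 116 in the order above. A gene that a filter removed was not tested under that setting. The fits without genes higher in epithelium tested 47 of the 83 genes in B and 72 of the 108 in CD4 T cells. Those without genes higher in the other gland lymphocytes tested 41 and 67. Values near the floor of the arrays and 3 or 4 arrays a group limit which changes can be called.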

Other observations

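The gene lists and their tests in this part were planned; the single values of spleen B cell replicate 3 were looked up only after the data were seen. The change of interleukin genes from spleen to gland was lower in B than in CD4 T cells in 6 of 20 (6 adjusted over the list alone; adjusted p = 0.00101, and 0.0163 with an estimated correlation). In CD4 T cells 5 of 20 rose between spleen and gland (5 adjusted over the list alone; adjusted p = 0.00667, and 0.0341 with an estimated correlation), among them Il2, a growth factor of T cells (4.31-fold), and Il18, an inducer of Ifng (4.98-fold), beside Il10 and Il21. In B cells 1 rose and 4 fell (1 and 4 adjusted over the list alone; list adjusted p = 0.757). The 4 included Il12a (-1.48), Il18 (-1.47) and Ebi3 (-1.06), and Il10 rose by 1.24. Il18 stood at 5.62 ± 0.33 (SD) in gland and 7.08 ± 0.26 in spleen B cells, and at 5.31 ± 0.15 and 3.0 ± 0.15 in CD4 T cells.

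Genes of the unfolded protein response rose in 2 of 17 in gland against spleen CD4 T cells (2 adjusted over the list alone; median 0.39, adjusted p = 1.43e-05, but adjusted p = 0.0751 with an estimated correlation). Xbp1, a transcription factor of that response, was 2.21-fold higher in gland CD4 T cells, and 4.50-fold higher in epithelium than in gland lymphocytes. Th17 genes rose in 3 of 8 (3 adjusted over the list alone; adjusted p = 0.00564, but adjusted p = 0.0691 with an estimated correlation), with the aryl hydrocarbon receptor gene Ahr at 4.35-fold. Genes of cholesterol synthesis had a median of -0.33 in CD4 T cells (adjusted p = 0.0091, but adjusted p = 0.0641 with an estimated correlation), and 1 of 13, Mvd, was called lower (1 adjusted over the list alone; -1.11, but -0.93 and no longer called with the mean of its probe sets). Ribosomal protein genes were not called in CD4 T cells (0 of 32 by limma, with 5 at an unadjusted p under 0.05; median -0.06, list adjusted p = 0.0586, and 0.00208 by fry) or in B cells (0 of 32 by limma, with 2 at an unadjusted p under 0.05; list adjusted p = 0.498, and 0.188 by fry).

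In replicate 3 of spleen B cells the neutrophil genes S100a8 and S100a9 stood at 9.63 and 9.72, against 3.59 and 4.98 in replicate 1 and 3.32 and 4.22 in replicate 2.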
